A study of Homo sapiens with 20 samples.

How the data were processed

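HAND1 and H3K4me3 were immunoprecipitated from formaldehyde-fixed, sonicated chromatin of KOLF2.C1 human induced pluripotent stem cells and of a HAND1 knockout line, with input and IgG samples beside them, per the labels' protocols. Groups were taken from the sample titles, which give the line, the antibody and the replicate number. The description field of some samples names the table of the other antibody, and the titles were used instead. The labels do not say what the BSA condition contains, nor whether replicates came from separate cultures.

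The submitters' processing notes list bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0 and the build hg38. The settings of these tools, the narrow or broad peak mode, the control library, any filter on blacklisted regions and the rule for a consensus peak are not given in the sources used here. The deposited tables hold 1 consensus set per antibody, annotated with the annotatePeaks program of HOMER, per the file headers. Coordinates (bp, hg38, 1-based) and signed distances to the TSS (bp, negative upstream) are as the authors deposited them. The deposited peak score is 0 for every peak, so it was not used to rank or filter. Which samples, and which of the 2 lines, entered each set is not given in the sources used here. A consensus set is the result of calling and merging, so its number of peaks depends on depth and thresholds, which are unknown here for both sets. Depth per sample is unknown.

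The distance and the nearest gene in the tables come from 1 transcript per gene, while the annotation label (promoter, exon, intron, TTS, intergenic) covers all transcripts. The labelled gene differed from the nearest gene in 30.8% of HAND1 and 30.9% of H3K4me3 peaks labelled as promoter. A peak has 1 nearest gene, so a promoter shared by a pair of genes counts for 1 of them only, and a peak nearest to a non-coding RNA counts for no protein-coding gene. "Without H3K4me3" means that no called H3K4me3 peak shares a base with the HAND1 peak.

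Gene symbols were matched to RefSeq genes of GRCh38.p14, directly or through older symbols. Matches were found for the nearest gene of 98.0% of HAND1 and 98.2% of H3K4me3 peaks next to a protein-coding gene. The background was 20037 protein-coding genes on assembled chromosomes. Before the data were examined, 15 gene lists with 372 entries were fixed, and 356 of their 357 distinct genes were in the background (LOR was not). In all, 15 genes belong to more than 1 list. The lists were extraembryonic mesoderm and mesenchyme, amnion, trophoblast, pluripotency, primitive streak and nascent mesoderm, endoderm, neural, cardiac mesoderm, blood and endothelium, epithelial-mesenchymal transition, BMP and TGF-β signalling, WNT signalling, HOX, housekeeping, and genes of other cell types.

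Promoter shares were compared with two-sided Fisher's exact tests over peaks, with Wilson 95% intervals. Overlap meant at least 1 shared bp and was set against 100 random placements of the HAND1 peaks on their own chromosomes, widths kept, without masking of assembly gaps or unmappable sequence. A HAND1 peak was distal when it lay more than 1 kb from the TSS and had no promoter label. Each gene list was compared with all other background genes by Fisher's exact test, with exact (Clopper-Pearson) intervals. The gene counted when it was the nearest gene of at least 1 HAND1 peak, or had an H3K4me3 peak within 1 kb of its TSS. The width of the widest H3K4me3 peak per gene was compared by a two-sided resampling test of the median with 100000 resamples. Each resample drew as many genes as the list held, with replacement, from all genes with a peak, list genes included. Adjustment was by Benjamini-Hochberg over the 15 lists, with a threshold of 0.05. Genes named in the text were chosen by a rule fixed before the data were examined. It takes HAND1, up to 4 genes of each list with the most HAND1 peaks, the 10 genes with the most HAND1 peaks and the 10 with the widest H3K4me3 peak within 1 kb of the TSS. Genes outside it are said to be chosen after their values were seen or are named as neighbours or members shared between lists.

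Random lists matched on locus size (10000, by decile) used the space between neighbouring protein-coding gene bodies, in place of the planned spacing of TSSs, because the gene table gives no strand. The other alternatives were windows of 10 kb and 50 kb for HAND1 and of 5 kb and 100 bp for promoters, peaks at or above the median width, autosomes only, other overlap rules, a background of genes with H3K4me3, and summed widths. Added after the data were examined were assignments by the label or by either gene end, lists without shared genes, distal peaks only, and HAND1 peaks without H3K4me3, all of them or the distal ones. A labelled gene was counted only if it was a background gene and the nearest gene of a peak in either set. By this rule 69.9% of HAND1 and 68.7% of H3K4me3 promoter labels had a symbol, so the assignment by label is partial.

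The tests were checked on simulated data. With a chance of a peak of 80% in 1 list and 35% elsewhere, the list test called that list in 99% of 100 draws over 20037 genes and called 0.429% of unchanged lists. Genes of the raised list were taken out of the other lists, and peaks did not depend on locus size. Calls that arise through shared genes or locus size were therefore not covered. For 24 genes with peaks widened 1.5-fold, the width test gave an unadjusted p under 0.05 in 91.5% of 200 draws, and in 5.5% of 2000 unchanged lists. For lists drawn from large loci with no further effect, 45% had an unadjusted p under 0.05 by Fisher's exact test and 1% against the matched lists. The chance of a peak was set there by the same deciles that the matching used. A planted overlap of 30.0% was recovered, which checks the counting only, because the other simulated peaks lay where no overlap was possible. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

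The comparisons of wild-type with knockout cells were not run, because the tables hold no value per sample, and the motif test was not run, because no genome sequence was used here.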

Results

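HAND1, a basic helix-loop-helix transcription factor of extraembryonic and cardiac mesoderm, was mapped by chromatin immunoprecipitation and sequencing in the human induced pluripotent stem cell line KOLF2.C1 and in a HAND1 knockout line, together with H3K4me3, the histone mark of active promoters. Cells were collected on day 4 of a culture that the labels call the BSA condition. Of the 20 samples, 12 came from wild-type cells and 8 from knockout cells. The wild-type line had 3 samples each for HAND1, H3K4me3, input chromatin and IgG, and the knockout line had 2 of each. The deposited results were 2 consensus peak sets, 1 per antibody, with positions and gene annotation. Neither set held a value for any single sample, its peak score was 0 for every peak, and the depth of each sample is unknown. A comparison of wild-type with knockout cells could therefore not be made for either antibody, and no value for the input or IgG samples could be set beside the peaks. The comparisons below are between the 2 peak sets and between groups of genes, so they have no replicate error. Intervals and p-values treat peaks or genes as the units and cover counting error only.

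HAND1 peaks lay at promoters and, about as often, away from them. The HAND1 set held 15607 peaks with a median width of 580 bp (interquartile range 433 to 810 bp). Of the 15581 peaks with a gene annotation, 7109 were labelled as promoter (45.6%, Wilson 95% interval 44.8 to 46.4%), 3676 as intron (23.6%) and 2843 as intergenic (18.2%). Exons held 1461 peaks (9.38%) and transcription termination sites (TTS) held 492 (3.16%). The nearest gene was protein-coding for 67.2% of HAND1 peaks, a long intergenic non-coding RNA for 18.3% and an antisense RNA for 14.4%. The H3K4me3 set held 12506 wider peaks, with a median of 769 bp (564 to 1089 bp). Of its 12498 annotated peaks, 7520 were labelled as promoter (60.2%), 1957 as intron (15.7%), 1714 as exon (13.7%), 995 as intergenic (7.96%) and 312 as TTS (2.5%).

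**Figure D1:**
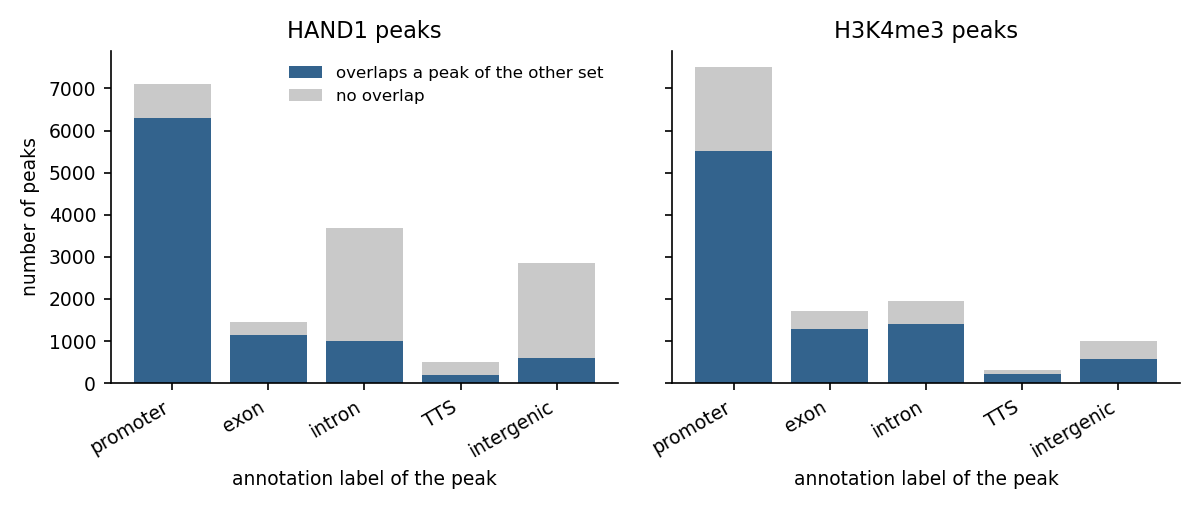
Number of HAND1 peaks (left) and H3K4me3 peaks (right) by annotation label, with the dark part of each bar showing peaks that share at least 1 bp with a peak of the other set. Most HAND1 peaks labelled as promoter (6308 of 7109) overlap H3K4me3, while most of those labelled as intron or intergenic do not.

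The first comparison asked how the genomic context of HAND1 differs from that of H3K4me3. HAND1 peaks were found near a transcription start site (TSS) less often. Within 1 kb of the nearest TSS lay 5466 of 15581 HAND1 peaks (35.1%, 34.3 to 35.8%) and 6669 of 12498 H3K4me3 peaks (53.4%, 52.5 to 54.2%). The difference was −18.3 percentage points, with an odds ratio of 0.472 (95% interval 0.450 to 0.496, two-sided Fisher's exact test, p = 8.70e-208). The test treats the sets as independent, although 59.1% of HAND1 peaks share a base with an H3K4me3 peak, so its interval and p-value are nominal. At the far end, 15.7% of HAND1 peaks and 8.42% of H3K4me3 peaks lay more than 50 kb from the nearest TSS. Within 100 bp the difference was −2.18 points (9.36% against 11.5%). The distance column used 1 transcript per gene, and 38.7% of the HAND1 peaks labelled as promoter lay more than 1 kb from the TSS it used.

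The second comparison asked how far HAND1 peaks coincide with the promoter mark. Of the 15607 HAND1 peaks, 9231 shared at least 1 bp with an H3K4me3 peak (59.1%, 58.4 to 59.9%). In 100 random placements on the same chromosomes the share was 0.723% ± 0.060 (SD over placements), with a highest value of 0.871% (one-sided permutation p = 0.0099, the smallest that 100 placements can give). The placements ignored gene density and unmappable sequence, so they set a low bar. The share was 88.7% for HAND1 peaks labelled as promoter, 77.5% for exons, 39.2% for TTS, 27.2% for introns and 20.9% for intergenic peaks. Among the 7366 HAND1 peaks that were more than 1 kb from the TSS and had no promoter label, it was 26.9%, against a mean of 0.684% in the placements. HAND1 peaks therefore fell into 7247 promoter peaks with H3K4me3 (46.5%), 968 promoter peaks without it (6.21%), 1981 distal peaks with it (12.7%) and 5385 distal peaks without it (34.6%). The promoter label reached only a short way downstream of a TSS. The closest peaks of CDX1 (136 bp), TGFBR2 (184 bp) and ID1 (217 bp) were labelled as exon. Distal peaks, above all those with H3K4me3, may therefore include peaks just downstream of a TSS that the distance column did not use. From the side of the mark, 9005 of 12506 H3K4me3 peaks overlapped a HAND1 peak (72.0%, 71.2 to 72.8%).

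Overlap rose with peak width in both sets. It went from 41.1% in the narrowest quartile of HAND1 peaks to 74.6% in the widest, and from 38.2% to 94.9% for H3K4me3 peaks. HAND1 peaks that overlapped the mark had a median width of 638 bp, against 501 bp for the others. For H3K4me3 the medians were 894 bp with and 537 bp without a HAND1 peak.

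**Figure D2:**
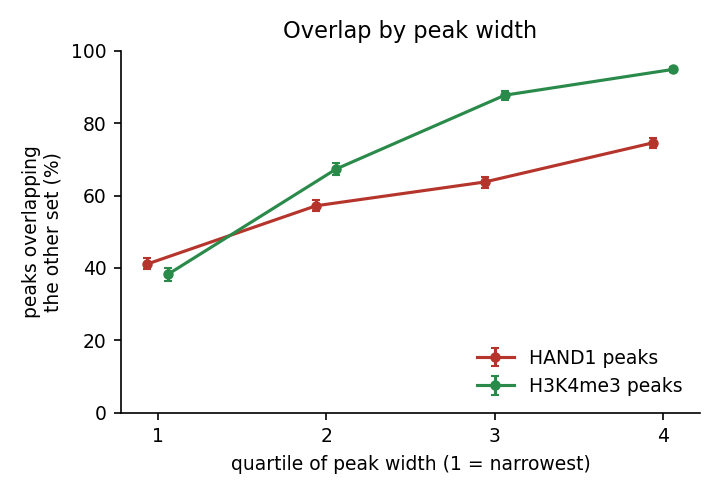
Share of peaks (%) that share at least 1 bp with a peak of the other set, by quartile of peak width from narrowest (1) to widest (4), for HAND1 and H3K4me3 peaks, with Wilson 95% intervals as bars. The share rises in each step, to 74.6% of HAND1 and 94.9% of H3K4me3 peaks in the widest quartile.

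The HAND1 gene itself (ENSG00000113196, hg38 chromosome 5, 154474972 to 154478227) had 3 HAND1 peaks. One lay in an exon (154477490 to 154478199, centred 420 bp downstream of the TSS) and coincided with an H3K4me3 peak at 154477422 to 154478172. Another, labelled as promoter (154478564 to 154479329, −682 bp), shared no base with H3K4me3. The last, intergenic (154479952 to 154480424, −1924 bp), coincided with the other H3K4me3 peak of the gene at 154479831 to 154480434. A further 12 HAND1 peaks lay beyond these, from 154482303 to 154618969, and were assigned to the long intergenic non-coding RNA AC026688.2. None of these 12 peaks overlapped an H3K4me3 peak. No other protein-coding gene lay within this 136.7 kb stretch, which began 4.08 kb from HAND1 and ended 64.0 kb before LARP1. Whether the peaks at HAND1 are lost in the knockout line cannot be read from the set.

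**Figure D3:**
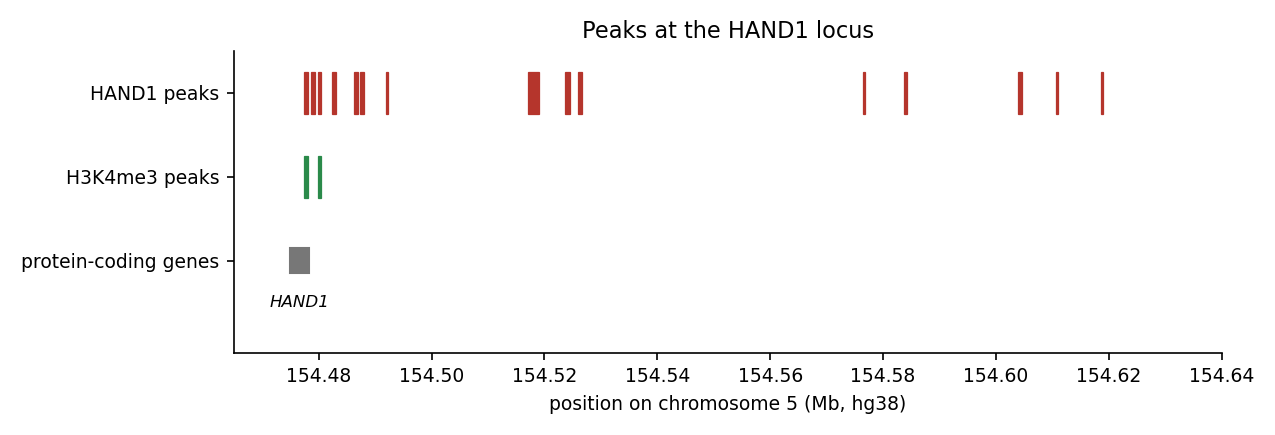
Map of HAND1 peaks (red), H3K4me3 peaks (green) and protein-coding gene bodies (grey) on chromosome 5 around HAND1, to scale in Mb of hg38. The 2 H3K4me3 peaks sit at HAND1, and 13 of the 15 HAND1 peaks lie between HAND1 and the right-hand end of the map and overlap no H3K4me3 peak.

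The third comparison asked which groups of genes lay next to HAND1 peaks. Genes of BMP and TGF-β signalling and of WNT signalling were the nearest gene of a HAND1 peak more often than other protein-coding genes. Of the BMP and TGF-β list, 26 of 31 genes had a peak (83.9%, exact 95% interval 66.3 to 94.5%, against 37.3% of other genes, adjusted exact p = 2.11e-06). SMAD6 and SMAD7, the inhibitory SMADs, had 6 and 5 HAND1 peaks, and ID1 and ID3, inhibitors of DNA binding that BMP induces, had 4 each. At SMAD6 the closest peak lay 464 bp from the TSS (chromosome 15, 66702858 to 66704225, exon), and at ID3 69 bp from it (chromosome 1, 23559142 to 23559606, promoter). Of the WNT list, 25 of 30 genes had a peak (83.3%, 65.3 to 94.4%, adjusted exact p = 2.38e-06). The ligand WNT4 had 9 HAND1 peaks, 7 of them without H3K4me3. The transcription factors LEF1 and TCF7L2 had 7 and 5 peaks, and the ligand WNT7B had 4. None of the 5 peaks assigned to TCF7L2 overlapped H3K4me3. The annotation label named TCF7L2 for 8 HAND1 peaks, so these 5 do not cover all HAND1 peaks at the gene. In the list comparisons, peak counts per gene are of peaks assigned to it as the nearest gene, at any distance. The farthest peak lay 148071 bp from the TSS for WNT4 and 194344 bp for LEF1.

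The amnion list and the extraembryonic mesoderm and mesenchyme list passed the same test. Of the amnion list, 16 of 20 genes had a peak (80.0%, 56.3 to 94.3%, adjusted exact p = 0.00105). The keratin gene KRT18 had 5, ID1 and ID3 had 4 each and WNT6 had 3. The amnion list shares ID1, ID2, ID3 and BAMBI with the BMP list and WNT6 with the WNT list. Without genes that belong to more than 1 list, its adjusted p was 0.0174. Of the extraembryonic mesoderm and mesenchyme list, 18 of 28 genes had a peak (64.3%, 44.1 to 81.4%, against 37.4%, adjusted exact p = 0.0196). The homeobox gene MSX2 and the collagen gene COL6A3 had 4 HAND1 peaks each, and the transcription factor genes GATA4 and TWIST2 had 3 each. The call for this list did not hold without shared genes (adjusted exact p = 0.131), against random lists matched on locus size (permutation p of 0.108), with only peaks at or above the median width (0.196) or by peaks within 1 kb of either end of the gene (0.768). Over all its alternatives the adjusted p ran from 0.000435 to 0.768. The log2 odds ratio of the list was 1.56 in the main comparison. It was 1.30 without shared genes and 1.24 with matching on locus size. With peaks at or above the median width it was 1.03, and by either gene end 0.388.

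The remaining 11 lists did not pass in this comparison, and 6 of them passed under at least 1 alternative. The cardiac mesoderm list had a peak at 13 of 21 genes (61.9%, adjusted exact p = 0.0730), with 6 at TBX3, 4 at the cardiac actin gene ACTC1 and 2 each at HEY2 and GATA5. The neural list reached 12 of 20 (60.0%, 0.131), with 5 peaks at DLX2 and 4 at SOX1, and the trophoblast list 13 of 22 (59.1%, 0.115), with 4 each at TEAD3, KRT19 and CCR7 and 3 at TFAP2C. Housekeeping genes had a peak at 15 of 27 (55.6%, 0.133), among them YWHAZ, GPI, PPIA and TUBB. Endoderm genes reached 11 of 20 (55.0%, 0.185), with 4 peaks each at SOX17 and the collagen gene COL4A1. Primitive streak and nascent mesoderm genes, and epithelial-mesenchymal transition genes, each had 10 of 22 (45.5%, 0.576), with 2 peaks each at WNT3, GSC and NODAL, and 3 at SNAI1. Pluripotency genes had 11 of 25 (44.0%, 0.576), with 2 each at KLF4, ZIC2 and OTX2. Blood and endothelium genes had 9 of 21 (42.9%, 0.654), with 2 each assigned to LMO2, CDH5, VWF and FLI1. The closest peak lay 58 bp from the TSS of LMO2, but 16203 bp from that of CDH5, 22861 bp for VWF and −25286 bp for FLI1. HOX genes had 12 of 39 (30.8%, 0.576), with 3 at HOXB1 and 2 at HOXB4. Genes of other cell types, chosen as silent in these lineages, had 5 of 23 (21.7%, 0.204), with 2 peaks at MYOD1. All p-values are from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists. Cardiac mesoderm passed with peaks within 10 kb (adjusted exact p = 0.0166) or 50 kb (0.0344) and when the labelled gene was counted too (0.00990), with a range of 0.00990 to 1 over its alternatives. With only peaks at or above the median width, trophoblast (adjusted exact p = 0.0124, range 0.00860 to 1), neural (0.0151, range 0.0151 to 0.745) and housekeeping genes (0.0213, range 0.0213 to 1) passed. By peaks within 1 kb of either end of the gene, epithelial-mesenchymal transition genes passed (adjusted exact p = 0.0320, range 0.0320 to 1). Endoderm genes, and again trophoblast and neural genes, passed with peaks without H3K4me3.

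Among genes that carried the promoter mark, the same 4 lists were compared again, with at most 18 genes each. Of the 5288 genes with an H3K4me3 peak within 1 kb, about 74.7% of those outside a list were nearest to a HAND1 peak, and none of the 4 lists passed against them (adjusted exact p = 0.166 for BMP and TGF-β, 0.433 for WNT and 0.745 for the amnion and the extraembryonic mesoderm and mesenchyme lists). All 18 marked genes of the BMP and TGF-β list, 17 of 18 of the WNT list, 8 of 8 of the amnion list and 12 of 13 of the extraembryonic mesoderm and mesenchyme list had one. The complete counts of the BMP and TGF-β and amnion lists had unadjusted exact p of 0.0110 and 0.215. With so few genes even a complete count did not pass here, so no conclusion is drawn from it. By HAND1 peaks within 1 kb of the TSS, the same 18 of 18 genes stood against 69.9% of other marked genes (adjusted exact p = 0.0452). This last test over the lists was not among the planned comparisons.

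HAND1 peaks without H3K4me3 lay next to genes of 7 developmental or signalling lists more often than next to other genes. Such peaks were nearest to 12 of 28 extraembryonic mesoderm and mesenchyme genes (42.9%, against 11.5% of other genes, adjusted exact p = 0.000435) and 9 of 20 amnion genes (45.0%, 0.00141). The shares were 11 of 30 for WNT (36.7%, 0.00165), 8 of 22 for trophoblast (36.4%, 0.00860), 7 of 20 for endoderm (35.0%, 0.0165), 9 of 31 for BMP and TGF-β (29.0%, 0.0173) and 6 of 20 for neural genes (30%, 0.0475). They were 1 of 27 for housekeeping genes (3.70%, 0.491) and 2 of 25 for pluripotency genes (8%, 0.816). All 4 peaks at COL6A3 and all 4 at CCR7 were of this kind, as were 3 of 4 at MSX2 and 5 of 6 at TBX3. This restriction to peaks without the mark was chosen after the data were examined. Without genes of more than 1 list, 5 lists passed. BMP and TGF-β genes (6 of 25, adjusted exact p = 0.115) and neural genes (6 of 20, 0.0555) did not. Their log2 odds ratios were 1.35 and 1.78 there, against 1.69 and 1.78 with shared genes. Against random lists matched on locus size, the extraembryonic mesoderm and mesenchyme (adjusted permutation p = 0.0150), amnion (0.0200), WNT (0.0200) and trophoblast (0.0232) lists passed, and endoderm (0.0948), BMP and TGF-β (0.227) and neural (0.216) did not. For these 3 lists the log2 odds ratio went from 2.09 to 1.55, from 1.69 to 0.978 and from 1.78 to 1.25 with the matching. Part of each fall comes from a small constant added to every count, because a matched list is only as long as the list itself. With only the distal peaks of this kind, 6 lists passed by Fisher's exact test, from amnion (8 of 20, adjusted exact p = 0.00375) to BMP and TGF-β genes (8 of 31, 0.0155), and neural genes did not (4 of 20, 0.233). Against lists matched on locus size none of the 15 passed with distal peaks (lowest adjusted permutation p = 0.0550), while 5 had an unadjusted p under 0.05. As a share of all HAND1 peaks next to list genes, peaks without H3K4me3 passed in none of the 15 lists (Fisher's exact tests, lowest adjusted p = 0.0893). A preference of list genes for peaks without the mark over HAND1 peaks with it was therefore not shown.

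**Figure D4:**
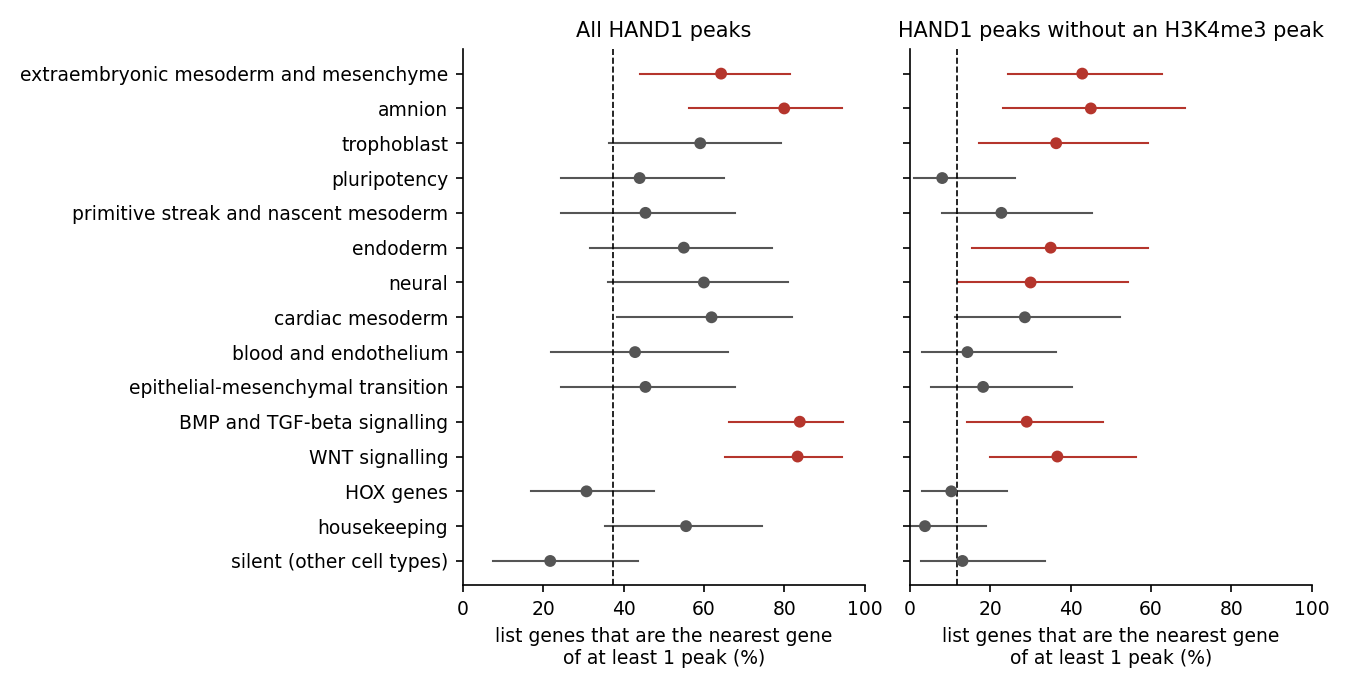
Share of the genes of each list (%) that are the nearest gene of at least 1 HAND1 peak (left) or of at least 1 HAND1 peak without H3K4me3 (right), with exact 95% intervals. The dashed line is the share among protein-coding genes outside the list (median over the lists), and red marks lists with an adjusted p under 0.05, 4 on the left and 7 on the right.

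The fourth comparison asked which groups of genes carried H3K4me3 at the TSS. WNT signalling genes (18 of 30, 60.0%, exact 95% interval 40.6 to 77.3%, adjusted exact p = 0.00160) and BMP and TGF-β genes (18 of 31, 58.1%, 39.1 to 75.5%, adjusted exact p = 0.00200) had a peak within 1 kb more often than other protein-coding genes (26.3%). Neither passed with a 100 bp window (adjusted exact p = 0.883 for both). There 4 of 30 WNT genes (13.3%) and 4 of 31 BMP and TGF-β genes (12.9%) had a peak, against 6.09% of other genes. The log2 odds ratios were 1.39 and 1.33 there, and 2.05 and 1.94 within 1 kb. The other 13 lists did not pass in this comparison. Their shares were 47.6% for cardiac mesoderm, 46.4% for extraembryonic mesoderm and mesenchyme, 45.5% for epithelial-mesenchymal transition, 44.4% for housekeeping and 40% for amnion genes, with adjusted p from 0.0866 to 0.337. They were 30% for neural, 27.3% for primitive streak and nascent mesoderm, 25.6% for HOX, 24% for pluripotency, 22.7% for trophoblast and 20% for endoderm genes, with adjusted p of 0.930 or 1. Blood and endothelium genes (1 of 21, 4.76%, adjusted exact p = 0.0866) and genes of other cell types (1 of 23, 4.35%, adjusted exact p = 0.0771) had the lowest shares. With a 5 kb window the blood and endothelium share was 28.6% (6 of 21) against 30.8% of other genes, so its low share was not kept there. The share of 44.4% at housekeeping genes limits what the absence of a peak can show. The peaks at GAPDH, named after its values were seen, were assigned to the transcript AC006064.3. By peaks within 1 kb of either end of the gene, the housekeeping share was 63.0%, against 49.8% of other genes (adjusted exact p = 0.352). In the same setting epithelial-mesenchymal transition genes passed with 21 of 22 (95.5%, adjusted exact p = 7.95e-05, range 7.95e-05 to 1 over the alternatives). Genes of other cell types passed with a lower share, 3 of 23 (13.0%, adjusted exact p = 0.00243, range 0.00243 to 1), and also when the promoter label was counted (adjusted exact p = 0.0377).

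H3K4me3 peaks were also wider at the same pathways. The median width of the widest peak per gene was 1296 bp over 24 BMP and TGF-β genes, against 817 bp over other genes with a peak (permutation test of the median, adjusted p = 0.000600). It was 1242 bp over 23 WNT genes (against 816 bp, adjusted permutation p = 0.00615). SMAD6 had a peak of 3623 bp, SMAD7 of 2454 bp and WNT4 of 1670 bp. The other 13 lists did not pass, except for neural genes with the summed width of all peaks of the gene (adjusted permutation p = 0.0485). Their medians ran from 542 bp for endoderm (8 genes, adjusted permutation p = 0.112) to 1118 bp for trophoblast genes (12 genes, 0.217). They were 751 bp for extraembryonic mesoderm and mesenchyme (0.685), 744 bp for amnion (0.646), 936 bp for pluripotency (0.571), 694 bp for cardiac mesoderm (0.571) and 1081 bp for epithelial-mesenchymal transition (0.276). Neural genes had 1009 bp, housekeeping 911.5 bp, HOX 699 bp and blood and endothelium 690 bp (0.571 each), primitive streak and nascent mesoderm 805 bp (0.946) and genes of other cell types 742 bp (0.819).

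The 10 genes with the most HAND1 peaks differed in how many of these carried H3K4me3. BCOR, a transcriptional corepressor gene on chromosome X, had 13 HAND1 peaks (40090100 to 40158715) and 12 H3K4me3 peaks, and 9 of the HAND1 peaks overlapped the mark. All 13 lay upstream of the TSS that the annotation used, and 11 were labelled as intron. AC084030.1, a long intergenic non-coding RNA gene, also had 13 HAND1 peaks (chromosome 2, 236691623 to 236876445), none with H3K4me3. This stretch lay 109 kb from ACKR3, a chemokine scavenger receptor gene that itself had 9 HAND1 peaks, 7 without H3K4me3. RHOU, an atypical Rho GTPase gene, had 12 HAND1 peaks, 9 without H3K4me3, and AC026688.2 next to HAND1 had 12. AL121820.2, an antisense transcript in RAD51B, had 11, all without the mark. ZMIZ1, a transcriptional coregulator gene, had 10 peaks, 9 of them without H3K4me3. AC109479.3 in ADAMTS2 also had 10, again 9 without it. The transcription factor genes KLF13 and NFATC2 had 10 and 9, of which 6 and 7 were without it. WNT4 also had 9 peaks but fell outside the 10 genes, because ties were broken by the distance of the closest peak to the TSS.

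The 10 genes with the widest H3K4me3 peak within 1 kb of a TSS included GATA2-AS1, CPEB2 and SMAD6. The widest, 3677 bp (chromosome 3, 128486601 to 128490277), was labelled as promoter of GATA2, a trophoblast and blood transcription factor gene, and assigned to its antisense transcript GATA2-AS1. It was followed by CPEB2, which encodes a translational regulator (3656 bp), SMAD6 (3623 bp), ZFP36L2, an mRNA decay factor (3546 bp), and ZSWIM6 (3529 bp). The antisense transcripts AL162497.1, AC007686.3 and AL355297.4 had 3383, 3231 and 3152 bp, the phosphodiesterase gene PDE10A had 3180 bp and the transcription factor gene SOX11 had 3102 bp. All 10 overlapped a HAND1 peak.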

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

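The tests of distal peaks and of transcripts per gene were chosen after their results were seen. The random placements were planned, but what they would show under each explanation was set down after their result was seen. The restriction to peaks without H3K4me3 was also chosen after the data were examined, and its test of locus size was set down before the result of that test was seen. The tests of marked housekeeping and lineage genes were chosen before their results were seen. A total of 31 HAND1 peaks and 8 H3K4me3 peaks lay off the assembled chromosomes, in sequence that no gene comparison used. The contig KI270733.1 held 10 HAND1 peaks and GL000224.1 held 4, the only 2 of 13 contigs with more than 3 peaks in either set, which is why they are listed. Neither had an H3K4me3 peak, but the HAND1 set is larger (15607 against 12506 peaks) and the difference between the sets was not tested. The tables give no value for IgG or input there.

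For the coincidence of HAND1 and H3K4me3 peaks, the observed overlap of 59.1% against at most 0.871% in random placements argues against uniformly random positions only. The placements ignored gene density and unmappable sequence, so they were a low bar. A pull-down that enriches any active promoter requires that marked housekeeping promoters carry a HAND1 peak at least as often as others, and they did, in 10 of 12 genes (83.3%, exact 95% interval 51.6 to 97.9%, against 70.0% of other marked genes), though 12 genes also allow a lower share. All 18 marked BMP and TGF-β genes had such a peak, against 69.9% of other marked genes (adjusted exact p = 0.0452). By nearest gene all 18 again had a peak, against 74.6%, a complete count that did not pass (adjusted exact p = 0.166). Their H3K4me3 peaks within 1 kb were wide (median 1368.5 bp, lower quartile 1091.5 bp). Of the widest quartile of all H3K4me3 peaks, 94.9% overlapped a HAND1 peak. Genes were not matched on peak width, so the 18 of 18 cannot be told apart from enrichment that rises with promoter strength. Binding directed at lineage promoters would give a higher share in the extraembryonic mesoderm and mesenchyme or amnion lists. It was 18 of 21 (85.7%, 63.7 to 97.0%, against 70.0%), too few genes to decide, so that specific binding and general enrichment cannot be told apart for these genes without values from the knockout libraries.

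For HAND1 peaks without H3K4me3 near list genes, locus size was weighed. Genes in large loci are the nearest gene of more peaks by position alone, which would leave no list past the threshold against lists matched on locus size. In that test 4 lists stayed past it (extraembryonic mesoderm and mesenchyme, amnion, WNT and trophoblast). For these 4, this argues against spacing between protein-coding genes, as matched by decile, as the whole cause. Size differences within a decile were not matched, nor were non-coding genes that take peaks as the nearest gene, so locus size in the wider sense stays open. For the endoderm, neural and BMP and TGF-β lists the call ended with the matching (adjusted permutation p of 0.0948, 0.216 and 0.227) while the log2 odds ratio fell from 2.09 to 1.55, from 1.78 to 1.25 and from 1.69 to 0.978, so locus size was neither excluded nor borne out there, and a HAND1-dependent cause, loss in the knockout, was not tested. For distal peaks alone no list passed (lowest adjusted permutation p of 0.0550, 5 lists with an unadjusted p under 0.05), with log2 odds ratios of 2.73 without and 1.91 with matching for amnion, 2.24 and 1.88 for trophoblast, 2.44 and 1.79 for endoderm, 2.25 and 1.44 for extraembryonic mesoderm and mesenchyme, 2.11 and 1.46 for WNT and 1.82 and 0.949 for BMP and TGF-β genes, so locus size stays open there too.

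The last pattern was the gap between promoter label and nearest gene. Of the 13703 gene identifiers in both tables, 0 were paired with more than 1 transcript, which is what a distance column built on 1 transcript per gene requires. No biological explanation was tested.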

How the results depend on the processing

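Settings that use peaks without H3K4me3, distal peaks, either gene end, the annotation label or lists without shared genes were chosen after the data were examined. The lower promoter share of HAND1 kept its sign and stayed past the threshold under all 5 alternatives (−18.4 to −2.18 points), and so did the overlap (26.9 to 60.0%). The overlap was 58.2% for HAND1 peaks at or above the median width against H3K4me3 peaks at or above theirs. The number of lists past the threshold for HAND1 was 4, and 3 to 6 under 10 alternatives. It fell to 0 against genes with H3K4me3, where the 15 lists keep at most 18 genes each. There even 18 of 18 genes did not pass. It also fell to 0 with distal peaks without H3K4me3 and matching on locus size, and rose to 7 with HAND1 peaks without H3K4me3. The cause of these last 2 changes was not tested. For H3K4me3 it was 2, then 0 with a 100 bp window and 4 within 1 kb of either gene end, and the cause was not tested. For width it was 2, and 2 or 3 under both alternatives.

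Values for single lists changed sign 26 times for HAND1, 17 for H3K4me3 and 5 for width, never for a list past the threshold, and the cause was not tested. Calls were gained 15, 3 and 1 times, and lost 14 times for HAND1 and 2 times for H3K4me3. As log2 odds ratios for HAND1, these were −0.057 (pluripotency) and −1.12 (blood and endothelium) with peaks at or above the median width, and 0.24 (HOX) within 10 kb. Against genes with H3K4me3 they were −0.72 (primitive streak), −1.03 (epithelial-mesenchymal transition) and 0.022 (other cell types). By either gene end they were −0.18 (primitive streak) and −1.37 (blood and endothelium). With peaks without H3K4me3 they were −0.30 (pluripotency), −1.21 (housekeeping) and 0.38 (other cell types), with or without shared genes. With matching on locus size they were −0.76, −1.01 and 0.44, and 0.52 for HOX. With distal peaks without H3K4me3 they were −2.39 (pluripotency), −0.86 (housekeeping) and 0.18 (other cell types), and with matching −2.94, −0.62 and 0.24, with −0.074 for blood and endothelium and 0.66 for HOX.

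For H3K4me3 with a 100 bp window they were −0.25 (extraembryonic mesoderm and mesenchyme), 0.24 (endoderm), 0.035 (HOX), −0.20 (housekeeping) and 0.035 (other cell types). With 5 kb they were 0.66 (trophoblast), 0.37 (pluripotency) and 0.20 (HOX). With wider peaks they were 0.15 (trophoblast), 0.37 (pluripotency), −0.34 (cardiac mesoderm) and 0.26 (HOX). With the promoter label they were 0.68 (trophoblast) and 0.13 (pluripotency). By either gene end they were −0.19 (extraembryonic mesoderm and mesenchyme), −0.50 (primitive streak) and −0.12 (cardiac mesoderm). The difference in median width became 177 bp (extraembryonic mesoderm and mesenchyme), 152.5 bp (endoderm) and 85 bp (blood and endothelium) with summed widths, and −17 bp (epithelial-mesenchymal transition) and 42 bp (HOX) within 1 kb.

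No paired analysis was possible because the tables hold no value per library. For the same reason the planned fits of wild-type against knockout samples, with other normalizations, a replicate block or 1 replicate left out, were not run. The motif alternatives were not run without a genome sequence. Peak width stood in for the constant score. Depth is unknown, so what it limits cannot be stated. The housekeeping share with an H3K4me3 peak was 44.4% within 1 kb of the TSS and 63.0% by either gene end. It therefore depends on the assignment of peaks to genes and is no measure of depth alone.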

Other observations

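All window counts, cluster counts and genes in this part were chosen after the data were examined. Around most genes, HAND1 peaks without H3K4me3 were absent. In a window of 150 kb to either side of the gene centre, 51.7% of 20037 protein-coding genes had none, the median was 0 and the 95th percentile was 4. HAND1 itself had 14 (17 HAND1 peaks in all), and 1 gene had more, the inhibitory SMAD gene SMAD7 with 15 (19 in all). The calmodulin-like genes CALML3 and CALML5, which are neighbours on chromosome 10, had 13 each, and ZMIZ1 had 12. Windows of neighbouring genes overlap, so these counts are not independent.

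Distal HAND1 peaks without H3K4me3 also formed clusters. With gaps of up to 12.5 kb joined, the 5385 peaks gave 22 clusters of 5 or more peaks (121 peaks), against at most 1 in 100 random placements. The largest had 7 peaks each, 1 at the receptor phosphatase gene PTPRF (chromosome 1, 43536283 to 43566237) and 1 next to AL138752.2 (chromosome 9, 38008315 to 38047998). Others with 6 peaks lay at HTRA3 (chromosome 4), between MANBAL and SRC (chromosome 20), at KRT80 (chromosome 12) and at AC093567.1 (chromosome 18, 48776833 to 48803007). The placements ignore gene density and unmappable sequence, so they are a low bar.

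Some genes of the fixed lists lacked both marks. POU5F1 and NANOG, core pluripotency transcription factor genes, and TBXT, the brachyury gene of the primitive streak, had 0 HAND1 and 0 H3K4me3 peaks within 3 kb of the gene body. GAPDH had 1 of each in the same window (HAND1 at chromosome 12, 6533455 to 6535206). With the sensitivity of the H3K4me3 set unknown, absence of a called peak does not show absence of the mark.

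Among HAND1 peaks next to list genes, the share without H3K4me3 was 17 of 30 for trophoblast (56.7%), 13 of 24 for endoderm (54.2%), 12 of 23 for cardiac mesoderm (52.2%), 18 of 35 for amnion (51.4%) and 18 of 38 for extraembryonic mesoderm and mesenchyme genes (47.4%). It was 3 of 6 for genes of other cell types (50%), 40% for HOX and 34.7% for BMP and TGF-β genes. It was 2 of 14 for pluripotency (14.3%) and 1 of 16 for housekeeping genes (6.25%), against 32.3% elsewhere. The remaining 5 lists lay between 35.7 and 46.2%. None of the 15 lists passed (two-sided Fisher's exact tests, lowest adjusted p = 0.0893, for trophoblast), and 5 had an unadjusted p under 0.05. A test among genes marked by H3K4me3 gave a HAND1 peak within 1 kb at 18 of 18 BMP and TGF-β genes against 69.9% of others (adjusted exact p = 0.0452), 17 of 18 WNT genes (adjusted exact p = 0.151) and no other list past the threshold. It was not among the planned comparisons, and genes were not matched on peak width. By nearest gene the BMP and TGF-β list did not pass (adjusted exact p = 0.166).

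One hypothesis is that part of the HAND1 peaks without H3K4me3 lies next to lineage genes for reasons other than locus size. It was consistent with the 4 lists that passed against lists matched on locus size, where for example 42.9% of extraembryonic mesoderm and mesenchyme genes were nearest to such a peak, against a mean of 16.0% in the matched lists. As a share of all HAND1 peaks next to list genes, peaks without H3K4me3 passed in none of the 15 lists (Fisher's exact tests, lowest adjusted p = 0.0893). The peaks without H3K4me3 include 968 at promoters, and the matching covered only the spacing between protein-coding genes, by decile. With the 5385 distal ones alone, none of the 15 lists passed against matched lists (lowest adjusted permutation p = 0.0550), so for distal sites it stays open. It was found and tested on the same data, and values per library in the knockout line would be needed to decide it.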
